A study of Mus musculus with 12 samples.

How the data were processed

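RNA from pooled left or right ventricles of 14.5 dpc mouse embryos (15 to 30 embryos per sample) was extracted with a column kit, and biotin-labelled cRNA made from 100 ng of it was hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds log2 expression values of 45101 probe sets on 12 arrays, made by the authors with RMA (background correction, quantile normalization and summary of the probes of a set), per the submitters' processing notes, which give no version. That the scale is log2 follows from RMA and from the values, which run from 2.42 to 15.19 with a median of 5.67 and have 2 decimals. Scanner files and detection calls were not analysed here, and the genome build and the annotation behind the probe sets are not given in the sources used here. RMA brings the arrays to one distribution, which can hide a shift shared by most genes and can move differences between arrays of unlike RNA composition. A deposited column was matched to each sample by its label, and 0 columns of per-sample values were left unused.

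Groups were taken from the labels: wild-type CD1 (WT) and Nos3-/- of strain B6.129P2-Nos3tm1unc/J (KO), each with left and right ventricle (LV and RV), 3 arrays per group. Of the probe sets 34958 had 1 gene symbol in the platform annotation, 932 several and 9211 none, and only those with 1 symbol named a gene. Their symbols were set against a RefSeq gene table of assembly GRCm38.p6 by gene ID, where 34754 matched and 0 symbols changed. That table also gave the order of genes along the chromosomes, and no coordinates were taken from it. For the 9012 genes with more than 1 probe set, the one with the highest mean over the 12 arrays was used, which left 18194 genes, with no filter on dim genes.

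Differences were tested with limma (lmFit and eBayes) in one model with a mean for each of the 4 groups, which share one estimate of the spread, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 5 comparisons were KO minus WT in each ventricle, the interaction of genotype and ventricle (right minus left), and right minus left ventricle in each genotype. A positive genotype difference means a higher value in KO. Adjusted p-values of genes are limma's, and those of gene lists come from limma's camera with its preset correlation of 0.01, adjusted over the 39 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Camera with an estimated correlation called 0 lists in every comparison, and the lowest adjusted p was 0.282, 0.487, 0.506, 0.337 and 0.0531 in the order given. Fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes, called 26, 0, 0, 1 and 6 lists. Nos3 and single technical measures were tested with two-sided exact permutation tests (scipy), in which 3 against 3 arrays cannot give a p below 0.1. For a called list, camera's direction, the median and the mean had the same sign in all 5 comparisons. The overlap of calls was set against n1 × n2 / N per direction. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

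The comparisons, the tests, the gene lists, the rule for named genes and the other settings to be tried were fixed before the data were examined. The rule named Nos3, Nnt, Nppa, Nppb, Hand1, Hand2, Tbx5, Nkx2-5, Gata4 and Notch1 in the genotype comparisons, with the 5 largest rises and the 5 largest falls among called genes whose groups do not overlap (chance gives 10% of genes without overlap). It also named up to 2 called members in each direction of the 8 lists with the largest share called and of every list that camera called. For the ventricle comparisons it named the 8 largest differences in each direction and all members of the lists for left ventricle and for right ventricle and outflow tract, and for the interaction up to 5 called genes in each direction. Predicted genes and clone names were passed over. Members of lists named beside these were chosen after their values were seen. The lists covered signalling, muscle and metabolic pathways and markers of other cell types and organs, and some members were not measured, as for ribosomal proteins (22 of 34 measured) and erythroid cells (16 of 22).

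Other settings tried were leaving out dim genes, quantile normalization once more, median centring of arrays, an intensity trend with robust variances, array weights, the replicate number as a fixed block or as a random block, the mean of the probe sets of a gene, every probe set on its own, stricter thresholds, the 2 compared groups alone, and leaving out each array. Chosen after seeing the data were a term for the poly-A control level, fits within the high-control or low-control arrays, leaving aside 2 arrays with extreme nuclear RNA, and, for gene lists, the replicate block and leaving out each array; the replicate block was also added for the overlap. The high-control and low-control arrays were set by the mean of the 24 poly-A control probe sets, at the gap of 0.42 between 8.47 and 8.89, and this division was chosen after seeing the data. A larger gap, 0.55 between 7.35 and 7.90, sets KO_RV replicate 1 alone apart and was passed over, since a set had to hold at least 2 arrays, and the low-control arrays span 1.11. The labels give the replicate numbers 1 to 3 in every group without saying what a number shares. As a check, the deviations of same-numbered arrays from their group means were correlated across genes. The correlations were 0.21, 0.29 and 0.26 between the ventricles of KO and 0.11, 0.26 and 0.31 between genotypes in the right ventricle, all over 0.1, so in these comparisons the numbers were taken as pairs, from the data and not from the labels. The model reported has no block, and the fit with it was run beside it.

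The fits were tested on simulated data of 18194 genes with the mean and spread of each real gene and no group differences, of which 200 were changed. In the left ventricle 68% of genes changed by 0.5 and 100% of those changed by 1 or more were called, with 9 unchanged genes called. With the control term 12% and 76% of genes changed by 0.5 and 1 were recovered. In the right ventricle 60% and 100% were recovered, and for the interaction 14% and 90%. A simulated batch effect alone (SD 0.4) on the high-control arrays gave 7164 calls between genotypes in the left ventricle, 0 with the control term, and 0 calls in the right ventricle. With no effect simulated, the left ventricle difference with the control term and the right ventricle difference within the low-control arrays had r = 0.363, since both use WT_RV replicates 1 and 2. Of 39 lists the 1 shifted by 0.3 was called and 0 others. Simulated genes varied independently of each other, so this does not show how many lists are called by chance where genes vary together. In the real data, splits that mix the genotypes called up to 20 lists in the left and 15 in the right ventricle, against 18 and 13 for the real groups. The number of arrays limits the precision of every value.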

Results

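Ventricular tissue of mouse embryos at 14.5 days post coitum, a stage at which the septum and the valves of the heart are being completed, was profiled on 12 Affymetrix arrays. Left and right ventricles (LV and RV) were dissected from wild-type CD1 embryos (WT) and from embryos homozygous for a targeted allele of Nos3 (KO; strain B6.129P2-Nos3tm1unc/J), the gene of endothelial nitric oxide synthase, which makes nitric oxide in endothelial and endocardial cells. The 4 groups held 3 arrays each, and each array carried RNA of a pool of 15 to 30 embryos. The pools are separate samples by their labels, so that p-values measure the spread between pools. All WT pools were CD1 and all KO pools were of the other strain, so in every comparison of genotypes the Nos3 allele and the strain background cannot be told apart. The design asks how ventricular expression differs between WT and KO embryos. Values are log2 expression, all differences are on that scale, and the 3 arrays per group limit the precision.

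Nos3 was called lower in KO than in WT in both ventricles, in the left not under every setting, but stayed well above the median of all values, 5.67. Its only probe set read 8.36, 8.39 and 8.30 in the 3 WT left ventricles and 7.95, 8.02 and 7.86 in the 3 KO left ventricles. Right ventricles read 8.72, 8.94 and 8.37 in WT and 8.23, 8.04 and 7.77 in KO. The difference was -0.41 in the left (8.35 ± 0.05 against 7.94 ± 0.08, SD, n = 3 each, limma adjusted p = 0.0376) and -0.66 in the right ventricle (8.68 ± 0.29 against 8.01 ± 0.23, n = 3 each, limma adjusted p = 0.00983). All 3 KO values lay below all 3 WT values in each ventricle, and the two-sided exact permutation p was 0.1 in both, the smallest that 3 against 3 arrays allow. The left ventricle call was lost without any 1 of the 6 arrays (differences of -0.45 to -0.37), with median centring (-0.31) and with 2 arrays of extreme nuclear RNA left aside (-0.35). It held in 8 of 17 alternatives (adjusted p 0.00646 to 0.203), and the right ventricle call in 17 of 17 (0.00107 to 0.049). Among the latter, the fit with the poly-A control term is the same as that without WT_RV replicate 3. Whether this probe set lies outside the disrupted part of the gene is not known, so its level is only a weak check of the labels.

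Array medians ran from 5.57 to 5.74 and correlations between arrays across genes from 0.970 to 0.997. The median gene had an SD of 0.12 in WT_LV, 0.13 in WT_RV, 0.10 in KO_LV and 0.10 in KO_RV. On the first principal component, which held 50.7% of the variance, KO arrays lay between 15.0 and 28.2 and the WT left ventricles between -26.8 and -23.7, whereas the WT right ventricles lay at -8.12, -10.5 and -29.4. The array that stood apart from its group, WT_RV replicate 3, also differed in the 24 probe sets for poly-A transcripts that are added to RNA before labelling. These controls averaged 8.89 to 8.96 in the 3 WT left ventricles and WT_RV replicate 3 (high-control arrays) and 7.35 to 8.47 on the other 8 arrays (low-control arrays). The 18 controls added only at hybridisation averaged 11.56 to 11.70 and 11.33 to 11.52 in the same sets of arrays. All WT left ventricles were high-control and all KO arrays low-control, so only WT_RV held both kinds, and a control term in the model rests on WT_RV replicate 3 alone. With that term the Nos3 difference was -0.87 in the left ventricle, where its call was lost, and -0.82 in the right ventricle, where it held.

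**Figure D1:**
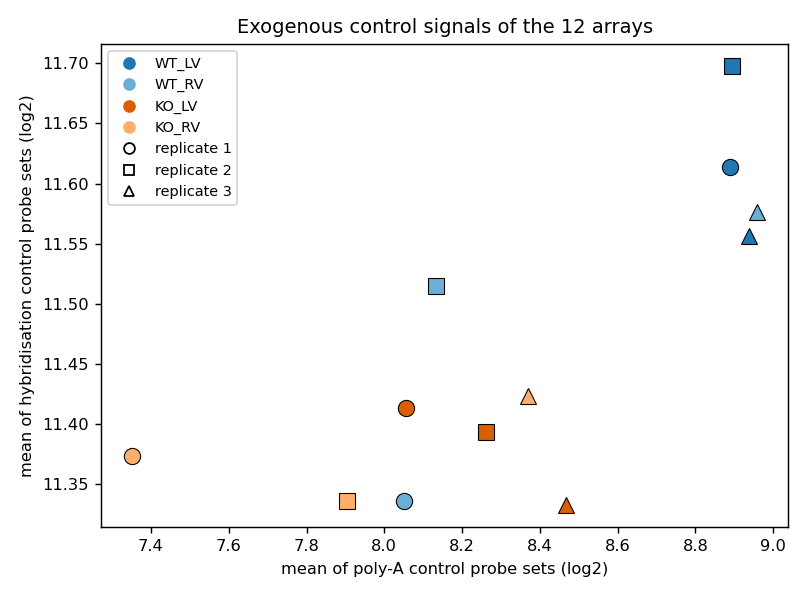
Mean log2 signal of the 18 hybridisation controls (vertical axis) against that of the 24 poly-A labelling controls (horizontal axis) on each of the 12 arrays, coloured by group. The 3 WT left ventricles and WT_RV replicate 3 lie at 8.89 to 8.96 on the horizontal axis and the other 8 arrays at 7.35 to 8.47.

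In the left ventricle, single genes of contraction, signalling and matrix were called higher in KO than in WT embryos. Myh6, the alpha-myosin heavy chain, rose from 11.67 ± 0.34 to 13.43 ± 0.16 (SD, n = 3 each), a difference of 1.76 (SE 0.19, adjusted p = 4.66e-05). Bmp2 and Bmp5, ligands that act in the forming valves and myocardium, rose by 1.54 (SE 0.12, adjusted p = 2.61e-06) and 1.54 (SE 0.13, adjusted p = 4.01e-06). The matrix genes Hapln1 and Vcan, which build the cardiac jelly, rose by 2.03 and 1.77, and the 2 cytochrome c oxidase subunit genes Cox7a1 and Cox8b fell by 1.25 and 1.04. With the control term the differences of Bmp2 (1.16) and Bmp5 (1.14) remained called, whereas Myh6 (1.07), Hapln1 (1.48), Vcan (1.02), Cox7a1 (-0.54) and Cox8b (-0.32) were not.

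The largest rises in the left ventricle were those of Vps52, a subunit of a vesicle tethering complex (4.37 ± 0.18 in WT, 8.21 ± 0.12 in KO, difference 3.84, SE 0.19, adjusted p = 4.15e-08), Rpgrip1, a protein of the photoreceptor cilium (3.49), Nxpe4 (3.33), Nipal4 (3.33) and Trim12a (3.28). The largest falls were those of Hddc3, a phosphohydrolase (10.42 ± 0.04 in WT, 6.95 ± 0.11 in KO, difference -3.47, SE 0.13, adjusted p = 1.18e-09), AI506816 (-3.43), Tmem87a, a Golgi membrane protein (-2.83), and Scg5, a chaperone of the secretory pathway (-2.47). All of these calls held with the control term, at 4.37 for Vps52, 2.53 for Rpgrip1, 3.38 for Nxpe4, 2.41 for Nipal4, 3.63 for Trim12a, -3.05 for Hddc3, -2.95 for AI506816, -2.68 for Tmem87a and -2.17 for Scg5. Other probe sets of some of these genes read otherwise, with -0.24 for Vps52, -0.09 for Trim12a, 0.07 for Hddc3, 0.31 for Nipal4 and -0.19 to 0.43 for the 3 others of Rpgrip1. Afp, a protein of fetal liver, was the remaining one of the 5 largest falls and is given with the liver genes.

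**Figure D2:**
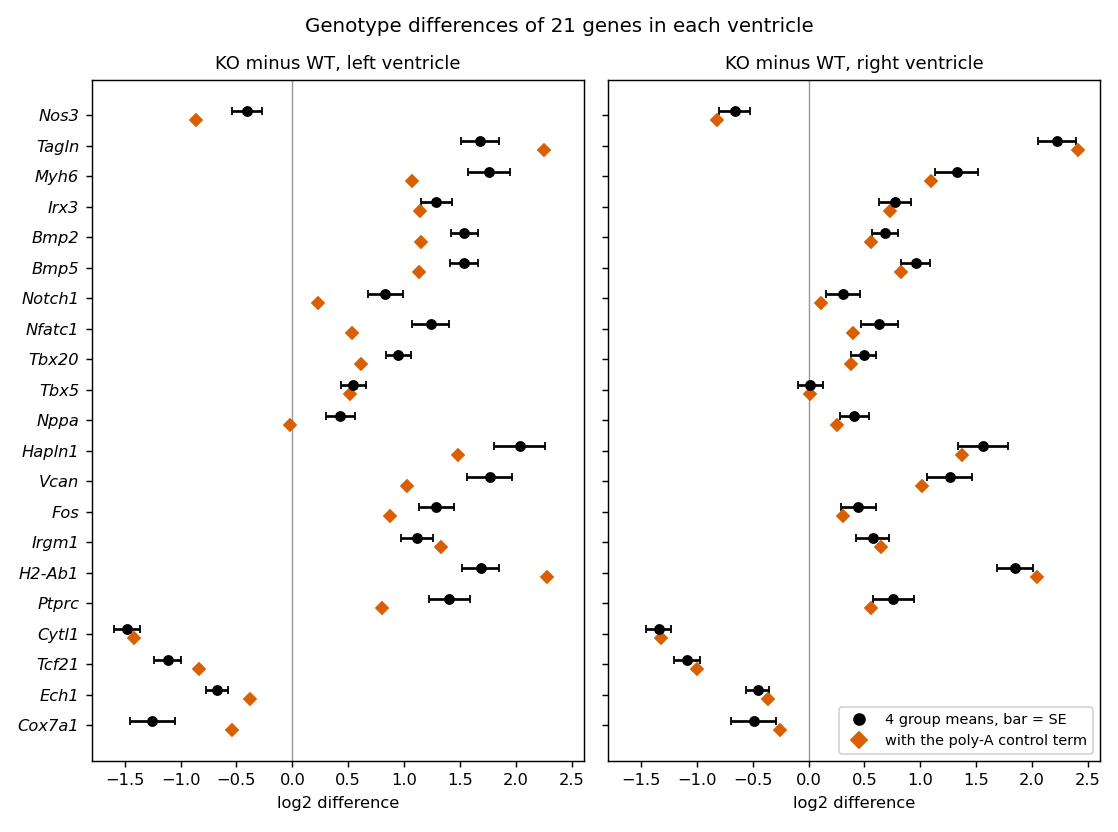
Log2 difference KO minus WT of 21 named genes in the left and the right ventricle. Black points with bars are the difference and its SE from the model with 4 group means, and orange diamonds are the same difference with the poly-A control term, for example 1.76 and 1.07 for Myh6 in the left ventricle.

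Regulators of heart muscle growth stood higher in the KO left ventricle. All 8 measured genes of compact myocardium rose, among them the transcription factors Tbx20 (0.95) and Prdm16 (0.93), and Fgfr1 (0.80). Among 30 cardiac transcription factors 15 rose and 1 fell, with Irx3 at 1.29, Nfatc1, a regulator of endocardial cushions, at 1.24, and the Notch target Hey1 at -0.40. Among 13 genes of trabecular myocardium 7 rose and 0 fell, including Gja5, the gap junction gene of the ventricular conduction system, at 0.77. Adjusted over the list alone, 8 of 8, 18 of 30 and 9 of 13 passed. Over all 18194 genes 3378 rose and 2239 fell in this ventricle, so 30.9% were called whatever the list. Camera gave adjusted p = 2.67e-05 for compact myocardium, 2.67e-05 for the transcription factors and 0.00471 for trabecular myocardium. Each had adjusted p = 0.282 with an estimated correlation. Splits of the arrays that mix the genotypes called up to 20 lists in this ventricle, against 18 for the real groups. List calls at the preset correlation, here and below, thus also arise without a genotype grouping. Under the control term the median shift of compact myocardium went from 0.73 to 0.26 and that of the transcription factors from 0.31 to 0.17, both still called, and that of trabecular myocardium from 0.43 to 0.22, no longer called. Tbx20 (0.62), Prdm16 (0.03), Irx3 (1.15), Nfatc1 (0.54), Hey1 (-0.40) and Gja5 (0.71) were each no longer called.

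Genes of signals between endocardium and myocardium stood higher as well. In BMP and TGF-beta signalling 19 of 33 genes rose and 3 fell, among them Smad2, a transducer of TGF-beta signals (-0.57), and Bmp4 (-0.48). In Wnt signalling 16 of 32 rose and 1 fell, with the inhibitor Apcdd1 at 1.27, the nuclear effector Lef1 at 1.05 and Dvl1 at -0.50. In Notch signalling 10 of 23 rose and 1 fell, with the ligand Dll1 at 0.97 and the receptor Notch1 at 0.83 (SE 0.15, adjusted p = 0.00146). Of 22 genes known from septal and valve defects 12 rose and 1, Mapk8, fell (-0.38). Adjusted over the list alone, 26, 18, 11 and 14 passed. Camera adjusted p was 7.34e-05 for BMP and TGF-beta, 0.000319 for Wnt, 0.00404 for Notch and 2.2e-05 for the septal and valve genes, against adjusted p = 0.282, 0.333, 0.282 and 0.282 with an estimated correlation. The median shifts with the control term went from 0.43 to 0.12 for BMP and TGF-beta and from 0.43 to 0.12 for the septal and valve genes, both still called, and from 0.36 to 0.12 for Wnt and 0.31 to 0.19 for Notch, no longer called. The term kept the call of Smad2 (-1.06) and ended those of Bmp4 (-0.26), Apcdd1 (0.73), Lef1 (0.95), Dvl1 (-0.44), Dll1 (0.51), Notch1 (0.23) and Mapk8 (-0.08). The other bright probe set of Smad2 read 2.05 where the one used read -0.57, so its direction depends on the probe set.

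Vessel, endocardial and connective tissue genes moved both ways. Of 26 endothelial genes 12 rose, led by Vwf, the clotting factor carrier (1.46), and the junction gene Cdh5 (1.08), and 3 fell, among them Gpihbp1, an anchor of capillary lipase, and Egfl7 (-0.69). Of 8 endocardial genes 6 rose, with Npr3, a natriuretic peptide receptor, at 0.98, and 1, Cytl1, fell (-1.48, SE 0.11, adjusted p = 2.48e-06). Of 31 genes of valve and interstitial mesenchyme 11 rose and 2 fell, the transcription factor Tcf21 (-1.12) and the matrix gene Lum (-0.52). Adjusted over the list alone, 17, 7 and 17 passed. By camera, adjusted p was 0.00942 for endothelium, 0.0277 for endocardium and 0.00496 for mesenchyme, and adjusted p = 0.445, 0.282 and 0.445 with an estimated correlation. In smooth muscle and pericytes 5 of 12 rose, led by Tagln, an actin-binding protein (1.68), and Cspg4 (0.76), and 2 fell, the pericyte genes Rgs5 (-1.46) and Kcnj8 (-1.13), and the list was not called. The control term kept the call of the mesenchyme list (median 0.31 without and 0.28 with it) and ended those of endothelium (0.32 and 0.13) and endocardium (0.46 and 0.30). It kept the calls of Tagln (2.25) and Cytl1 (-1.42), turned Gpihbp1 to 0.06, and left Vwf (0.77), Cdh5 (0.51), Egfl7 (-0.20), Npr3 (0.39), Tcf21 (-0.83), Lum (-0.17), Cspg4 (0.14), Rgs5 (-0.74) and Kcnj8 (-0.54) without a call.

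Leukocyte and interferon genes were higher in KO left ventricles. Of 18 genes of macrophages and leukocytes 12 rose and 0 fell, among them Laptm5 (1.47), Ptprc, the pan-leukocyte surface antigen (1.40), Ctss (1.31) and the macrophage growth factor receptor Csf1r (1.13). Of 21 interferon response genes 12 rose and 0 fell, including the GTPase Irgm1 (1.11) and Usp18 (1.01), and of 12 genes of antigen presentation 3 rose and 0 fell, including H2-Ab1 (1.69) and Tapbp (0.46). Adjusted over the list alone, 14, 12 and 3 passed. The 3 of 12 called in antigen presentation are a smaller share than the 30.9% called over all genes. By camera, adjusted p was 9.74e-06, 0.0015 and 0.0489 for the 3 lists, and adjusted p = 0.282, 0.282 and 0.445 with an estimated correlation. All 3 lists remained called with the control term, at medians of 0.69, 0.52 and 0.30 in place of 0.51, 0.40 and 0.19. Csf1r (1.13), Irgm1 (1.33) and H2-Ab1 (2.28) remained called, and Laptm5 (0.83), Ptprc (0.80), Usp18 (0.77) and Tapbp (0.31) did not.

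Genes of mitochondrial energy supply were lower. In oxidative phosphorylation 0 of 40 measured genes rose and 16 fell (21 adjusted over the list alone), and in fatty acid oxidation 0 of 25 rose and 12 fell (13 over the list alone), with Ech1 at -0.67 and Etfb, a subunit of the electron transfer flavoprotein, at -0.58. For these lists camera adjusted p was 1.36e-05 and 0.00195, and adjusted p = 0.282 and 0.363 with an estimated correlation. Both lists with the control term remained called, at medians of -0.14 and -0.23 in place of -0.19 and -0.22, with no single call among Cox7a1, Cox8b, Ech1 (-0.38) and Etfb (-0.27). Of 22 cytosolic ribosomal protein genes 4 fell and 0 rose (4 over the list alone), among them Rpl14 (-0.71, -0.45 with the control term) and Rps18 (-0.31, -0.01 with the term), both without a call there. Its 4 of 22 calls were a smaller share than the 30.9% called over all genes. That list had camera adjusted p = 0.0162, and adjusted p = 0.445 with an estimated correlation. It was not called with the control term (median -0.13 without and -0.00 with it).

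Transcripts of other organs differed between the left ventricular pools. Of 13 liver and lung genes 4 fell and 0 rose (4 over the list alone). Over all genes 30.9% were called in this ventricle, so 4 of 13 is no excess of calls. The list had a median of -0.55 and camera adjusted p = 0.0162, and adjusted p = 0.445 with an estimated correlation. Alb and Afp, abundant proteins of fetal liver, were at 7.07 ± 0.87 and 7.67 ± 1.19 in KO and 9.33 ± 1.14 and 10.09 ± 1.20 in WT left ventricles (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). Their differences, -2.26 and -2.42, were -3.21 and -3.65 with the control term and not called there, while the list remained called. Nuclear noncoding transcripts (Malat1, Meg3, Kcnq1ot1 and Airn) averaged 9.73 in KO and 10.73 in WT left ventricles (exact permutation p = 0.3), with 8.64 in KO_LV replicate 3 and 11.26 in WT_LV replicate 2. Of 25 immediate early and heat shock genes, which respond within minutes to handling and stress, 13 rose and 0 fell (14 over the list alone), with Fos at 8.21 ± 0.20 in KO and 6.92 ± 0.12 in WT and Btg2 at a difference of 1.09. That list had camera adjusted p = 2.67e-05, and adjusted p = 0.282 with an estimated correlation. Its call (median 0.32 without and 0.08 with the term) and those of Fos (0.87) and Btg2 (0.25) ended with the control term.

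Several genes central to ventricular development did not pass the test in the left ventricle, with Hand1 at 0.03 (adjusted p = 0.9), Hand2 at 0.20 (0.0801), Nkx2-5 at -0.03 (0.864), Gata4 at 0.31 (0.151), Nppb at -0.14 (0.531) and Nnt, which is disrupted in some C57BL/6 substrains, at 0.10 (0.604). A second probe set of Nnt, about as bright, read 11.93 ± 0.12 in WT and 11.50 ± 0.17 in KO left ventricles (SD, n = 3 each), a difference of -0.43, so that the probe sets of Nnt differ. Tbx5 rose by 0.54 (SE 0.11, adjusted p = 0.00281) and Nppa, atrial natriuretic peptide, by 0.43 (SE 0.13, adjusted p = 0.0226), neither called with the control term, under which Nppa read -0.03. Among genes given for left ventricle and atrial identity, Cited1 rose by 0.68 and Kcnj3 by 0.89, and Fgf12 fell by 0.39, at 0.22, -0.04 and -0.17 with the control term and no longer called. Camera called none of the lists of sarcomere, smooth muscle, epicardium, erythroid, atrial, left ventricle, right ventricle and outflow tract, conduction, neural crest, retinoic acid, NO and cGMP, cell cycle, apoptosis, glycolysis, hypoxia, antioxidant, strain-variable, sex-linked and skeletal muscle genes or of the neighbours of Nos3. In the sarcomere list 12 of 31 rose and 3 fell (adjusted p = 0.0829). Of genes called in the left ventricle, another probe set above the median of all values read 0.09 for Apcdd1, 0.06 for Laptm5, 0.04 for Mapk8, 0.06 for Ndrg1, -0.05 for Olfm1, -0.12 for Tapbp and 0.06 for Tbx20, while further ones read 1.26 and 1.20 for Apcdd1, 0.84 for Laptm5, -0.79 and -0.31 for Mapk8, -0.61, -0.46 and -0.32 for Ndrg1 and 1.07 for Tbx20.

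Over all 18194 genes, 3378 were higher and 2239 lower in KO left ventricles (limma adjusted p under 0.05, 30.9% of genes), of which 269 and 112 differed by 1 or more. With each array centred on its median, 77.9% of the calls were higher in place of 60.1%. Under the control term 134 genes were higher and 63 lower, 181 of them called in the same direction without it, while the SE of the median gene rose from 0.11 to 0.18. With WT_LV replicate 2 and KO_LV replicate 3, the arrays with the most and the least nuclear noncoding RNA, left aside, 1720 were higher and 1018 lower.

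**Figure D3:**
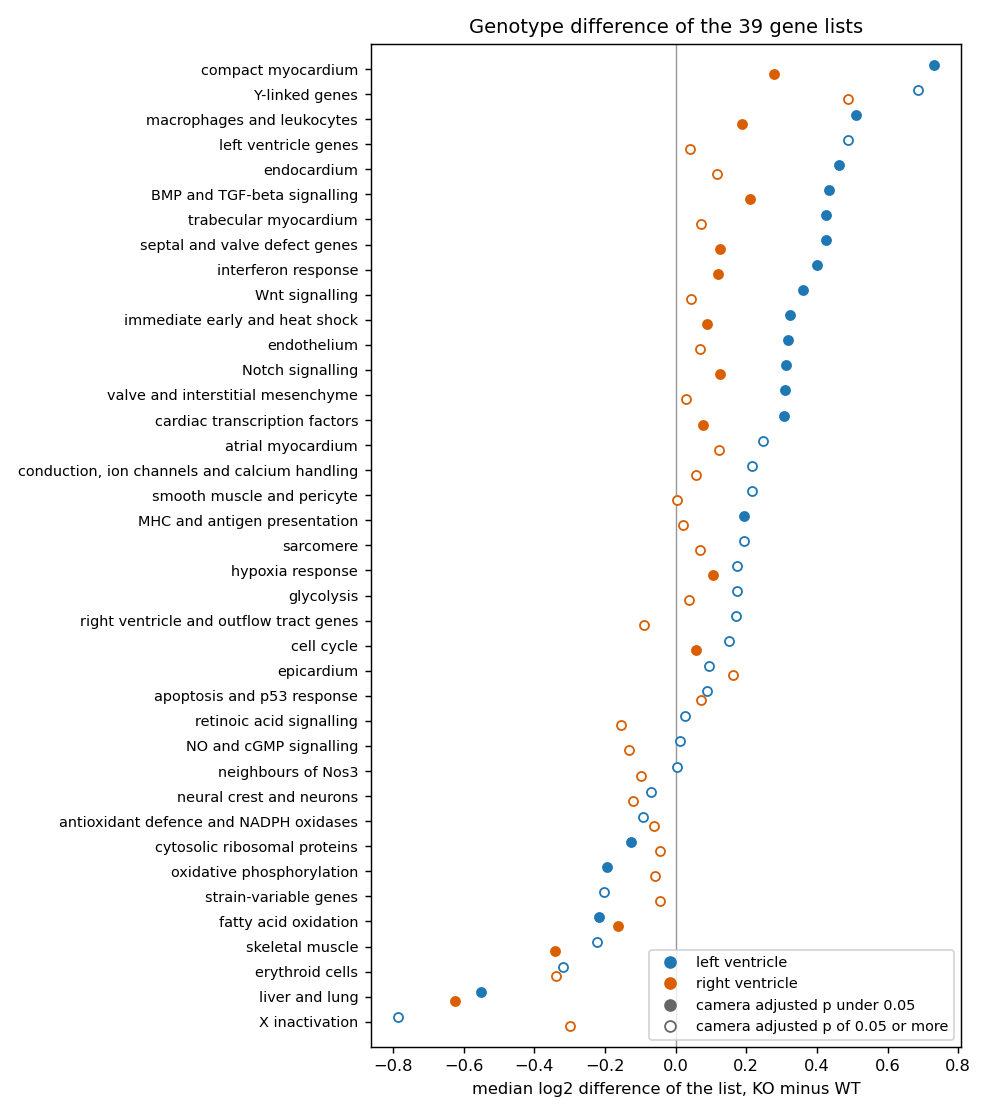
Median log2 difference KO minus WT of the measured members of 39 gene lists in the left (blue) and right (orange) ventricle, filled where limma's camera gave an adjusted p under 0.05 with its preset correlation. Of 39 lists 18 are filled for the left and 13 for the right ventricle, and 0 of them passed with an estimated correlation, where the lowest adjusted p was 0.282 and 0.487.

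In the right ventricle the largest difference belonged to Dcpp1, a secreted protein of salivary glands, at 9.18 ± 0.61 in WT and 4.03 ± 0.17 in KO (SD, n = 3 each, difference -5.15, SE 0.23, adjusted p = 1.41e-08). Nts, the precursor of neurotensin, rose from 7.18 ± 0.25 to 10.02 ± 0.23 (2.84, SE 0.13, adjusted p = 2.64e-08). Vps52 (3.26), Trim12a (2.86), Odr4 (2.86) and Rpgrip1 (2.84) were the other largest rises, and AI506816 (-3.31), Hddc3 (-2.87), the kainate receptor subunit Grik3 (-2.73) and Scg5 (-2.52) the other largest falls. Within the 8 low-control arrays, which leave 2 WT against 3 KO right ventricles, all 10 remained called, at -4.84 for Dcpp1, 2.97 for Nts, 3.44 for Vps52, 2.98 for Trim12a, 2.52 for Odr4, 2.52 for Rpgrip1, -3.15 for AI506816, -2.73 for Hddc3, -3.09 for Grik3 and -2.42 for Scg5. Other probe sets of these genes again read otherwise, with -0.16 for Vps52, 0.01 for Trim12a, -0.18 for Hddc3, 0.59 for Odr4 and -0.23 for Grik3.

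Several of the developmental genes called in the left ventricle were called here too. Myh6 rose by 1.33 (SE 0.19, adjusted p = 0.000871), Bmp5 by 0.96 and Bmp2 by 0.68, and Smad2 (-1.16) and Bmp4 (-0.44) fell. In BMP and TGF-beta signalling 7 of 33 rose and 2 fell, in compact myocardium 3 of 8 rose and 0 fell, including Tbx20 (0.49) and the cyclin Ccnd2 (0.45), and among septal and valve genes 4 of 22 rose and 0 fell. Among cardiac transcription factors 5 of 30 rose and 0 fell, with Irx3 at 0.77 and Nfatc1 at 0.63, and in Notch signalling 3 of 23 rose and 0 fell, with Dll1 at 0.64 and the sheddase Adam17 at 0.43. Adjusted over the list alone, 10, 4, 7, 7 and 5 passed. Over all genes 838 rose and 652 fell in this ventricle (8.19% called). Camera adjusted p was 0.00487, 0.00487, 0.00487, 0.0163 and 0.022 for these 5 lists, and adjusted p = 0.487 with an estimated correlation for each. Splits of the arrays that mix the genotypes called up to 15 lists in this ventricle, against 13 for the real groups. Within the low-control arrays compact myocardium (median 0.28 over all and 0.21 over these arrays) and the septal and valve genes (0.13 and 0.04) remained called, and the BMP (0.21 and 0.06), transcription factor (0.08 and 0.04) and Notch lists (0.13 and 0.06) did not. Myh6 (1.10), Bmp5 (0.82), Bmp2 (0.56), Smad2 (-1.32), Irx3 (0.73), Nfatc1 (0.40) and Dll1 (0.49) remained called there, and Bmp4 (-0.37), Tbx20 (0.38), Ccnd2 (0.33) and Adam17 (0.28) did not. The other bright probe set of Smad2 read 1.95, one of Tbx20 -0.32, and those of Adam17 -0.12 and -0.02, and Adam17 was called in 5 of 17 alternatives.

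Macrophage, interferon, cell cycle and hypoxia genes stood higher in the right ventricle of KO embryos. Of the 13 genotype list calls in this ventricle, above and below, 8 ended when dim genes were left out. The 8 are not named here, so no single list call in this ventricle can be taken to hold under that setting. Of 18 macrophage genes 4 rose and 0 fell, among them the complement gene C1qb (0.92) and Ptprc (0.76), and of 21 interferon genes 5 rose and 0 fell, with Gbp3 at 0.58 and Irgm1 at 0.57. Of 34 cell cycle genes 3 rose and 0 fell, including the cyclin Ccne2 (0.59), and of 21 hypoxia genes 3 rose, with the glucose transporter Slc2a1 at 0.80 and Pfkfb3 at 0.44, and 1, Ndrg1, fell (-0.58). Adjusted over the list alone, 6, 11, 3 and 7 passed. The 3 of 34 cell cycle genes called lie near the 8.19% called over all genes. Camera adjusted p was 0.00487, 0.00487, 0.022 and 0.0163, and adjusted p = 0.487 with an estimated correlation for each of the 4. Within the low-control arrays the macrophage (median 0.19 over all and 0.19 over these arrays), interferon (0.12 and 0.16) and hypoxia lists (0.11 and 0.13) remained called, and cell cycle (0.06 and 0.03) did not. Of the named genes C1qb (1.00), Gbp3 (0.51), Irgm1 (0.65), Ccne2 (0.75), Slc2a1 (0.70), Pfkfb3 (0.48) and Ndrg1 (-0.56) remained called there and Ptprc (0.56) did not. Of 25 immediate early genes 1 rose, Ier3 (0.42), and 1 fell, Egr3 (-0.36), with 1 over the list alone. That list had camera adjusted p = 0.0265, and adjusted p = 0.612 with an estimated correlation. Within the low-control arrays neither the list (median 0.04) nor either gene was called, and the other probe set of Egr3 read 0.43. Fos was at 7.31 ± 0.30 in KO and 6.87 ± 0.24 in WT right ventricles (n = 3 each, exact permutation p = 0.1).

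Fatty acid oxidation, skeletal muscle and liver genes stood lower. In fatty acid oxidation 0 of 25 rose and 4 fell (6 over the list alone), among them Ech1 (-0.46) and the mitochondrial carrier Ucp3 (-0.44), and of 8 skeletal muscle genes 1, the myosin heavy chain Myh8, fell (-0.83; 4 over the list alone). For these lists camera adjusted p was 0.00551 and 0.022, and adjusted p = 0.487 with an estimated correlation for both. Both lists remained called within the low-control arrays (medians -0.18 and -0.37, against -0.16 and -0.34 over all), as did Ech1 (-0.36) and Myh8 (-0.86), while Ucp3 (-0.36) did not. Of 13 liver and lung genes 0 rose and 0 fell in limma's test, and 0 adjusted over the list alone, at a median of -0.62 and camera adjusted p = 0.022, and adjusted p = 0.612 with an estimated correlation, and it remained called within the low-control arrays (-0.85). Alb and Afp averaged 8.50 and 9.22 in KO and 9.83 and 10.53 in WT, with 11.57 and 12.37 in WT_RV replicate 1 (exact permutation p = 0.3 for both). Erythroid genes, of which 6 of 16 fell and 0 rose, including the haem synthesis gene Alas2 (-1.22), were not called as a list (adjusted p = 0.0686, and adjusted p = 0.65 with an estimated correlation), but were called lower within the low-control arrays (median -0.415, against -0.34 over all).

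Among the genes chosen for their part in the ventricles, Nppa (0.41, adjusted p = 0.0682, called with the replicate number as a block), Nppb (0.19), Hand1 (-0.31), Hand2 (-0.00), Tbx5 (0.02), Gata4 (0.09), Notch1 (0.31), Nnt (-0.01, and -0.44 on the second probe set) and Nkx2-5 (-0.33, adjusted p = 0.0756) did not pass in the right ventricle, though Nkx2-5 was called within the low-control arrays (-0.40). Of the genes given for right ventricle and outflow tract, Sema3c, a guidance cue of the outflow tract, rose by 0.55 (0.58 within the low-control arrays) and Rspo3 by 0.68 (0.73, not called there). The endocardial genes Npr3 (0.51) and Cytl1 (-1.34) were called, and within the low-control arrays Cytl1 alone of the pair was. From the list of genes that vary between strains, Wdfy1 fell by 2.18 and Alad by 1.26.

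Over all genes 838 were higher and 652 lower in KO right ventricles (8.19%), 100 and 55 of them by 1 or more, and with each array centred on its median 69.5% of calls were higher in place of 56.2%. Within the low-control arrays 644 were higher and 493 lower, 945 of them called in the same direction over all arrays. Higher calls numbered 447, 529 and 456 without KO_RV replicates 1, 2 and 3 and 556 without WT_RV replicate 3, and lower calls 315, 375, 380 and 411.

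Genotype calls overlapped between the 2 ventricles. Called in both were 727 genes higher and 409 lower in KO, where independent lists would share 156 and 80.2, and 0 genes were called in opposite directions. With the control term the overlap of genotype calls between ventricles, higher in KO, was 117, and the overlap of genotype calls between ventricles, lower in KO, was 58, and leaving out each array in turn gave 404 to 979 and 223 to 426. Of the right ventricle calls 76.2% were also called in the left ventricle and 97.7% had the same sign there. Across genes, which are not independent replicates, the differences had r = 0.752 with a slope of 0.556 for right on left. Without the control term the 2 differences share no arrays, but their tests use the same estimate of the spread of a gene, which can raise the overlap of calls. With the term both estimates use the WT_RV arrays and so share their noise, and whether left and right ventricles came from the same embryos is not stated.

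Whether the genotype difference depended on the ventricle was tested as an interaction, the difference in the right minus that in the left ventricle. It was called for 4 genes, each with a KO minus WT difference that was lower in the right than in the left ventricle. With the replicate number as a block, taken as pairs between KO but not between WT ventricles, Dcpp1 alone was called. Dcpp1 was at 5.43 ± 0.26 in WT and 4.02 ± 0.14 in KO left ventricles and at 9.18 ± 0.61 and 4.03 ± 0.17 in the right ventricles, an interaction of -3.74 (SE 0.32, adjusted p = 0.00033). The other 3 were called higher in KO in the left and not in the right ventricle: Tcf24, a helix-loop-helix factor (-1.60, SE 0.19, adjusted p = 0.00784), Gpnmb, a glycoprotein of macrophages and melanocytes (-1.25, SE 0.17, adjusted p = 0.0208), and Gfra1, a receptor for glial cell line-derived factors (-1.22, adjusted p = 0.0332). With the control term Dcpp1 remained called (-4.36), whereas Tcf24 (SE 0.23 in place of 0.19), Gpnmb (-1.38) and Gfra1 (-1.16) were not, at differences about as large as without it, which for Tcf24 lay between -1.73 and -1.45 in all 21 alternatives.

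By list, the interaction was called for 14 of 39. Oxidative phosphorylation (median 0.15) and cytosolic ribosomal proteins (0.10) had the higher difference in the right ventricle. Cardiac transcription factors (-0.26), macrophages and leukocytes (-0.29), trabecular and compact myocardium, BMP and TGF-beta, Wnt, septal and valve, endothelial, endocardial, mesenchymal, immediate early and interferon genes had the lower. None was called with an estimated correlation, at adjusted p = 0.652 for endothelium, mesenchyme and ribosomal proteins and 0.506 for the other 11. Under that term 6 lists were called, 4 of them among the 14, namely macrophages (median -0.43), mesenchyme (-0.26), oxidative phosphorylation (0.08) and interferon response (-0.26). Over all genes 0 were higher and 4 lower in limma's test, with 2537 at an unadjusted p under 0.05. Without WT_RV replicate 3 the numbers became 499 and 810, and with array weights 517 and 847.

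Left and right ventricles of WT embryos differed most in Dcpp1 (3.75 higher in the right, SE 0.23, adjusted p = 3.78e-06) and in Wif1, a secreted Wnt antagonist, which rose from 4.74 ± 0.29 in the left to 7.10 ± 0.38 in the right (SD, n = 3 each, 2.36, SE 0.19, adjusted p = 3.53e-05). Muscle genes were among the other rises, with the skeletal actin gene Acta1 at 1.76, the calcium store protein Casq1 at 1.73 and the M-band protein Myom2 at 1.38, next to Robo1, a Slit receptor (1.48), the deiodinase Dio2 (1.32) and Olfm1 (1.31). Gtsf1, a factor of the piRNA pathway, fell from 12.36 ± 0.10 to 10.15 ± 0.36 (-2.21, SE 0.17, adjusted p = 3.53e-05), followed by Igfbp2 (-1.48), the cysteine dioxygenase Cdo1 (-1.19), Chn2 (-1.11), Dclk3 (-1.04), Lypd6b (-0.99), Rnase4 (-0.96) and Nrn1 (-0.90). With the control term Dcpp1 (4.37), Wif1 (1.92), Acta1 (1.85), Dio2 (1.18), Gtsf1 (-1.85), Igfbp2 (-1.58), Cdo1 (-1.63), Chn2 (-1.25), Dclk3 (-1.03) and Nrn1 (-1.14) remained called, and Casq1 (2.00), Robo1 (0.81), Myom2 (1.05), Olfm1 (0.80), Lypd6b (-0.86) and Rnase4 (-0.62) did not. In this comparison every value with the control term, here and below, is the difference of WT_RV replicate 3 from the mean of the WT left ventricles. Calls with the term therefore rest on 1 right ventricle array. The fit within the 4 high-control arrays gives the same differences and is not a separate check. With 1 right ventricle array, assumed to vary like the 3 left ventricles that give the spread, it says little about single genes.

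Of the 6 genes given for left ventricle identity, Nppa fell in the right ventricle of WT embryos by 0.59 (adjusted p = 0.0499, -0.89 and called with the control term, but called in only 8 of 18 alternatives, with adjusted p from 0.0186 to 0.553), while Tbx5 (-0.49, adjusted p = 0.0564), Gja5 (-0.38), Nppb (-0.30), Cited1 (-0.22) and Hand1 (0.10) did not pass. Of the 11 for right ventricle and outflow tract Sema3c rose by 0.90 (0.96 and called with the control term) and 10 did not pass, Hand2 among them at 0.27 (adjusted p = 0.141). The left ventricle list stood lower in the right ventricle (2 adjusted over the list alone, camera adjusted p = 0.00093, and adjusted p = 0.337 with an estimated correlation). It remained called with the control term (median -0.34 without and -0.47 with it). The right ventricle list stood higher (2 over the list alone, camera adjusted p = 0.0408, and adjusted p = 0.602 with an estimated correlation). It was not called with the control term (median 0.16 and 0.19). Splits that mix the WT ventricles called up to 16 lists, against 9 for the real groups.

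Sarcomere genes stood higher in the WT right ventricle, with 2 of 31 called, both higher, 11 over the list alone and a median of 0.22 (camera adjusted p = 3.72e-05, and adjusted p = 0.337 with an estimated correlation), and it remained called with the control term (0.08). Fatty acid oxidation, 2 of 25 higher, Pdk4 (0.55) and Acadvl (0.46), and 6 over the list alone, had camera adjusted p = 0.0004, and adjusted p = 0.602 with an estimated correlation, and it remained called with the term (median 0.18 without and 0.19 with it). In glycolysis 0 of 21 were called by limma and 3 over the list alone, with camera adjusted p = 0.0004, and adjusted p = 0.602 with an estimated correlation, and the call ended with the term (0.19 and 0.10). In BMP and TGF-beta signalling 2 of 33, Bmp5 (0.78) and Bmp2 (0.70), were higher (5 over the list alone), and in endothelium 1 of 26, Vwf (1.04, 1 over the list alone). These 2 lists had camera adjusted p = 0.0161 and 0.0279, and adjusted p = 0.664 and 0.853 with an estimated correlation, and with the control term camera's direction turned to lower, uncalled, while their medians stayed above 0 (0.04 for both). Epicardium, of which 1 of 15, Tbx18 (-0.43), was lower (3 over the list alone, median -0.39), and ribosomal proteins, with 0 of 22 called and 0 over the list alone (median -0.11), stood lower at camera adjusted p = 4.38e-07 and 0.000119. Both had adjusted p = 0.602 with an estimated correlation, and neither was called with the control term (medians 0.01 and -0.02). Over all genes 139 were higher and 40 lower in the right ventricle, against 19 and 15 with the control term, 22 of those 34 called in the same direction without it. Without WT_RV replicate 3 there were 1169 and 565, and without replicates 1 and 2 of that group 45 and 17, and 55 and 14. Without replicate 3 the WT right ventricles are all low-control and the left all high-control, so ventricle and control level cannot be told apart.

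Left and right ventricles of KO embryos, all low-control arrays, again differed most in Wif1, which rose from 5.10 ± 0.21 to 7.78 ± 0.19 (SD, n = 3 each, 2.68, SE 0.19, adjusted p = 5.28e-06), and in Gtsf1, which fell from 13.07 ± 0.15 to 10.38 ± 0.31 (-2.70, SE 0.17, adjusted p = 5.28e-06). The fast skeletal troponin Tnni2 (2.27), the relaxin receptor Rxfp1 (1.84), Myom2 (1.63), Casq1 (1.61), the receptor subunit Gabra4 (1.36), the water channel Aqp4 (1.32) and Wnt16 (1.18) were the other largest rises. Tcf24 (-1.98), Cdo1 (-1.97), Chn2 (-1.85), Nrn1 (-1.79), Lypd6b (-1.62), Tmem88b (-1.59) and Lgals3 (-1.57) were the other largest falls. Of the left ventricle genes 4 of 6 fell in the right ventricle: Tbx5 from 9.79 ± 0.23 to 8.77 ± 0.13 (-1.02, SE 0.11, adjusted p = 0.000242), Gja5 (-1.32), Cited1 (-0.83, called in 12 of 17 alternatives, adjusted p 0.00869 to 0.128) and Nppa (-0.61, in 10 of 17, 0.00812 to 0.167), while Nppb (0.03) and Hand1 (-0.24) did not pass. Sema3c rose by 0.98, and the other 10 genes for right ventricle and outflow tract did not pass. The control term leaves these differences as they are, since it does not vary among the KO arrays.

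Energy and sarcomere genes stood higher in the KO right ventricle. In oxidative phosphorylation 1 of 40, Cox6a2 (0.62), was higher (15 adjusted over the list alone), in fatty acid oxidation 3 of 25, including the lipid transporter Cd36 (0.63), were higher (14 over the list alone), and in sarcomere 3 of 31, with Acta1 at 1.12, were (6 over the list alone). Camera adjusted p was 8.02e-18, 3.78e-11 and 2.82e-05, and adjusted p = 0.0846, 0.0979 and 0.114 with an estimated correlation. Glycolysis and the liver and lung list, with medians of 0.04 and 0.28, 1, Eno3 (0.58), of 21 and 0 of 13 members called, and 2 and 0 over the list alone, had camera adjusted p = 0.0441 and 0.0455, and adjusted p = 0.594 and 0.617 with an estimated correlation. Both lost their calls with the control term.

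Macrophage, trabecular and left ventricle genes stood lower in the KO right ventricle. Of 18 macrophage genes 3 fell, Ctss (-0.91), Csf1r (-0.69) and Cd68 (-0.52), and 13 passed over the list alone, and of 13 trabecular and 6 left ventricle genes 3 and 4 fell (5 and 4 over the list alone). Camera adjusted p was 2.21e-13, 1.21e-06 and 7.12e-08, and adjusted p = 0.0856, 0.0531 and 0.0531 with an estimated correlation. Mesenchyme, with Col2a1, a cartilage collagen, higher (1.17) and Fbln1 lower (-0.96), and immediate early genes, with Fos lower (-0.89), had camera adjusted p = 6.27e-09 and 7.7e-06, and adjusted p = 0.3 and 0.32 with an estimated correlation (11 of 31 and 1 of 25 over the list alone). Epicardium, with Tbx18 at -0.86, and Wnt signalling, with Wif1 higher and Wnt5a (-0.77) and Sfrp5 (-0.83) lower, had camera adjusted p = 5.89e-05 and 0.00128, and adjusted p = 0.464 with an estimated correlation for both (3 of 15 and 4 of 32 over the list alone). Compact myocardium (0.000373) and interferon response (0.00648) had adjusted p = 0.328 with an estimated correlation, with 0 members of either called and 2 and 2 over the list alone. Cardiac transcription factors (0.00223, 2 lower, 3 over the list alone) had adjusted p = 0.409 with an estimated correlation. Septal and valve genes (0.00722, 1 lower, 2 over the list alone), Notch signalling (0.0474) and cell cycle (0.0185), the last pair with 0 members called, had adjusted p = 0.464 with an estimated correlation.

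**Figure D4:**
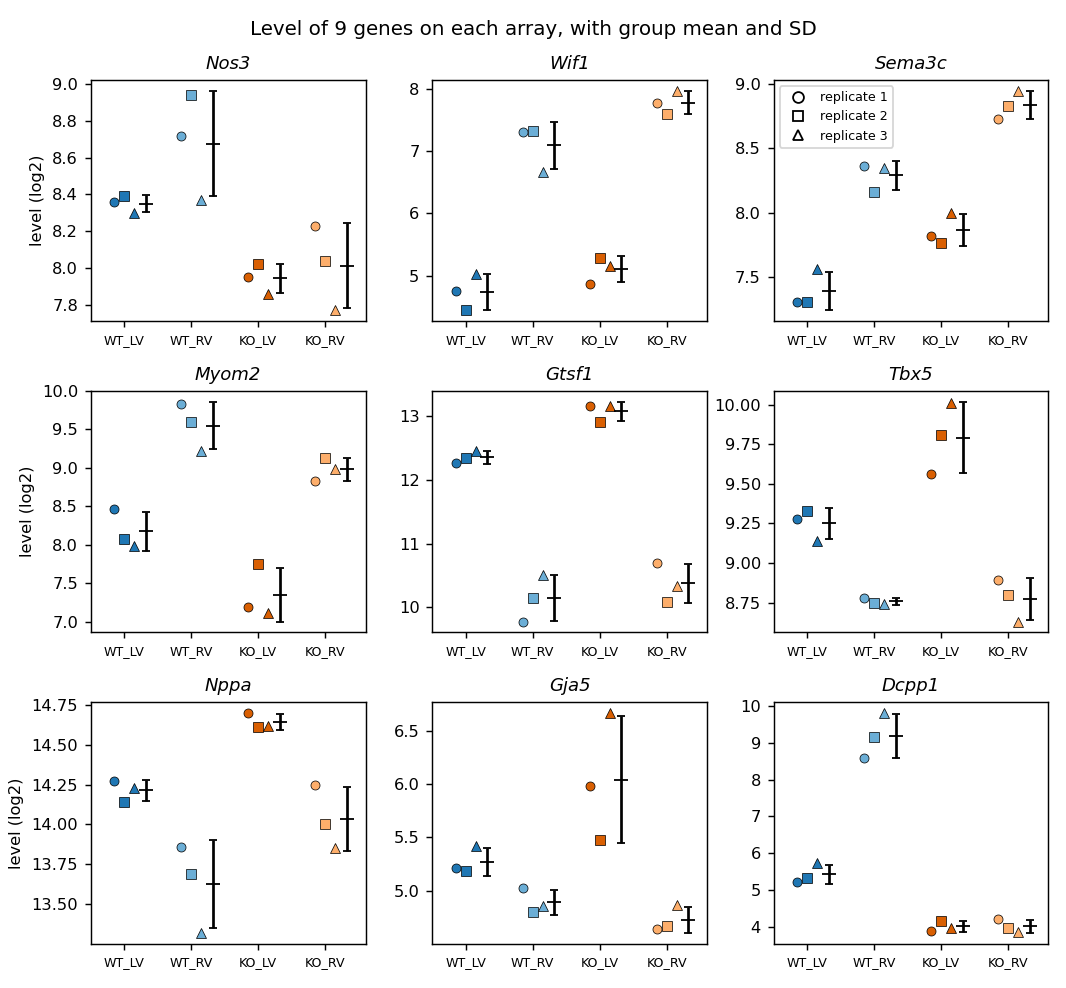
Log2 level of Nos3, Wif1, Sema3c, Myom2, Gtsf1, Tbx5, Nppa, Gja5 and Dcpp1 on each of the 12 arrays, with the mean and SD of each group of 3. Wif1 is higher and Gtsf1 lower in the right than in the left ventricle of both genotypes, and Dcpp1 is high in the WT right ventricle alone, at 9.18 ± 0.61.

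Over all genes 100 were higher and 108 lower in the right ventricle of KO embryos, and leaving out each of the 6 arrays in turn left 47 to 59 and 49 to 80. Between the genotypes, 42 genes were higher and 19 lower in the right ventricle of both, where independent lists would share 0.764 and 0.237, and 0 were called in opposite directions. Both tests use the same estimate of the spread of a gene, which can raise the overlap, so the lists are not independent. Of the KO calls 89.9% had the same sign in WT, and 90.4% within the high-control arrays, where WT_RV replicate 3 was the only right ventricle, while across all genes the ventricle differences of the genotypes had r = 0.169 (genes are not independent replicates).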

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

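Chosen after the results had been seen were the tests with the poly-A control term, those with 2 arrays of extreme nuclear RNA left aside, the comparisons of control levels, and the tests by which the ratio of left to right ventricle calls is weighed, whereas the interaction, the list tests, the other settings and the splits of the arrays were planned.

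The genotype difference differed between the ventricles by a test of the interaction for 4 genes, Dcpp1 (-3.74), Tcf24 (-1.60), Gpnmb (-1.25) and Gfra1 (-1.22). Over 21 alternatives the adjusted p ran from 1.22e-05 to 0.00575 for Dcpp1, which was called in all 21, from 0.00211 to 0.122 for Tcf24 (called in 19), from 0.00704 to 0.163 for Gpnmb (13) and from 0.00336 to 0.334 for Gfra1 (7). Among lists the interaction had adjusted p = 0.00186 for cardiac transcription factors, 0.0307 for trabecular myocardium, 0.00326 for compact myocardium, 0.00188 for BMP and TGF-beta signalling, 4.03e-04 for Wnt signalling, 0.00188 for septal and valve defect genes, 0.0115 for endothelium, 0.0213 for endocardium, 0.00481 for valve and interstitial mesenchyme, 5.26e-05 for macrophages and leukocytes, 1.76e-06 for oxidative phosphorylation, 4.03e-04 for immediate early and heat shock genes, 0.0456 for interferon response and 0.0115 for cytosolic ribosomal proteins. Each of these had adjusted p = 0.506 or 0.652 with an estimated correlation. Chance cannot be excluded for either count: 11 of 100 splits of the arrays gave as many genes (4, highest other 465) and 11 of 100 as many lists (14, highest other 18), the real split among them. Most of the others with as many kept the ventricles of KO whole or exchanged them whole. Ventricle differences enter the contrast in such splits, so these shares are not a clean chance value. The split with 465 genes kept the WT groups in place and exchanged the ventricles of KO, so that it measures the ventricle difference common to both genotypes, and it points to a structure of the samples. The split that exchanged WT_RV replicate 3 with WT_LV replicate 3, both high-control arrays, gave 22 genes and 17 lists.

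The poly-A labelling controls, which no comparison of groups uses, stood 0.85 higher on 4 arrays (the 3 WT left ventricles and WT_RV replicate 3, mean 8.92) than on the other 8 (mean 8.07). The hybridisation controls were higher on the same 4 arrays, and there are 495 ways to pick 4 of 12 arrays.

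More genes were called between genotypes in the left (5617) than in the right ventricle (1490), a ratio of 3.77. The ratio was 4.12 after a further quantile normalization and 4.48 with median centring. Both start from values that RMA had already normalized, so they cannot tell whether normalization between arrays accounts for the ratio. For a labelling batch that follows the poly-A controls, the difference of the low-control from the high-control arrays within WT_RV correlated across genes (not independent replicates) with the left ventricle genotype difference (r = 0.527), and 84.0% of the left ventricle calls shared its sign, against 61.7% for KO_RV replicate 3. The KO_RV arrays, meant as a reference without a control difference, differ in these controls too: replicates 1 and 3 stood at -0.785 and 0.742 from the other KO_RV arrays, next to 0.868 for WT_RV replicate 3, yet gave r of only 0.0378 and 0.114 (-0.158 for replicate 2), which goes against an effect graded with the control level and leaves open a batch of the 4 high-control arrays, seen within a group in 1 array alone. With the control term the ratio was 0.204, where the SE in the left ventricle was 1.65 times as large. A genotype effect that differs between the ventricles cannot be told apart from this batch, since every WT left ventricle was a high-control array, and with the term 1 gene was called for the interaction.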

How the results depend on the processing

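All tests with the poly-A control term, within the high-control or low-control arrays, with 2 arrays of extreme nuclear RNA left aside, with the replicate block for gene lists and for the overlap, and with each array left out for gene lists were chosen after the data had been seen, and the others were planned.

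Under alternatives named genes kept side of the threshold in 2909 fits, lost calls in 297, gained calls in 21 and reversed in 6. For gene lists these counts were 2169, 179, 62 and 3. Direction was compared only where a gene or list was called under the main model or the alternative. Uncalled genes whose sign turned count as kept, as for Hand1 in the left ventricle (-0.2 to 0.158 over alternatives). Calls held in 10 or fewer alternatives for Afp (10), Dvl1 (9), Fgf12 (9), Lum (8), Nos3 (8) and Rps18 (10) between genotypes in the left ventricle, for Adam17 (5), Bmp4 (8), Egr3 (8), Ier3 (5), Nfatc1 (10), Npr3 (9), Rspo3 (8), Tbx20 (10) and Ucp3 (7) in the right, for Gfra1 (7 of 21) in the interaction, and for Nppa between WT (8 of 18) and KO ventricles (10), each of 17 unless given and of 16 for Fgf12. Counts are given as higher then lower, and the cause of a change was not tested unless the setting itself gives it. Every probe set on its own gave 5759 and 4727 in the left ventricle and 1301 higher in the right, from more features tested. An adjusted p under 0.01 left 2101 and 992 in the left ventricle, 327 and 206 in the right, 2 lower for the interaction, 47 and 13 between WT ventricles and 48 and 45 between KO ventricles. A difference of 1 or more left 269 and 112, 100 and 55, 25 and 6 (WT ventricles) and 20 and 23 (KO ventricles). Median centring left 1212 lower in the left and 374 in the right ventricle and 24 between WT ventricles, with Nos3 at -0.31 in the left ventricle, not called. Array weights gave 1352 and 1506 in the right ventricle, 517 and 847 for the interaction, 1435 and 777 between WT and 317 and 367 between KO ventricles, and weighted WT_RV replicate 3 lowest (0.293). The compared groups alone gave 537 and 391 in the right ventricle, 29 and 12 between WT ventricles and 170 lower between KO ventricles. An intensity trend with robust variances gave 1 higher for the interaction and the mean of probe sets 2 lower. That mean turned Smad2 to 0.74 in the left and 0.40 in the right ventricle and Egr3 to 0.0367 in the right. Leaving out dim genes left 5 lists in the right ventricle. Camera with an estimated correlation called 0 lists in each of the 5 comparisons, against 18, 13, 14, 9 and 18.

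With the poly-A control term there were 134 and 63 calls in the left ventricle, 556 and 411 in the right, 1 lower for the interaction, 19 and 15 between WT and 154 and 167 between KO ventricles, and 6 lists for the interaction. For genotypes in the right ventricle the term sets WT_RV replicate 3 aside, so this is the same fit as the one without that array. The fit within the low-control arrays leaves that array out too, so these are not separate checks. The overlap of genotype calls between ventricles, higher in KO, was 117, and the overlap of genotype calls between ventricles, lower in KO, was 58. Nos3 was at -0.87 in the left ventricle, not called (adjusted p over 17 alternatives 0.00646 to 0.203, called in 8; in the right ventricle 0.00107 to 0.049, called in 17). Nppa turned to -0.025, Kcnj3 to -0.035 and Gpihbp1 to 0.055. Between WT ventricles camera's direction turned for compact myocardium (adjusted p = 0.0319), BMP and TGF-beta signalling (0.920) and endothelium (0.920). Within the 4 high-control arrays 1 and 0 were called between WT ventricles, with 1151 at an unadjusted p under 0.05 in limma, and within the 8 low-control arrays 167 and 199 between KO ventricles. Without the 2 arrays of extreme nuclear RNA there were 1720 and 1018 in the left ventricle, 2 lower for the interaction, 41 and 11 between WT and 51 and 45 between KO ventricles, with Nos3 at -0.35 in the left ventricle, not called.

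With the replicate block the interaction had 1 lower gene, and the block moved no other count by over 1.5 times. It took the interaction call from Tcf24, Gpnmb and Gfra1 and the call of endothelium between WT ventricles, and added calls for Nppa in the right ventricle, conduction and hypoxia in the left, and Notch signalling for the interaction. In all of these but Nppa and the interaction the numbers were not taken as pairs, and for the interaction they were taken as pairs between KO but not between WT ventricles. This fixed block changed no other call. Correlations of same-numbered arrays were 0.23, -0.01 and 0.15 between WT ventricles and 0.01, 0.14 and 0.42 between genotypes in the left ventricle. As a hint from the data, each array correlated best with its own number in 3 of 3 pairs between KO ventricles and between genotypes in the right ventricle, in 2 of 3 between WT ventricles and in 1 of 3 between genotypes in the left. A random block of the pools gave 339 and 96 between WT ventricles, with a call for Tbx5 there and none for Adam17 and Ier3 in the right ventricle between genotypes.

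Leaving out each array in turn gave 2487 to 3242 higher and 1421 (without KO_LV replicate 2) to 1849 lower in the left ventricle, 15 to 20 lists, and Nos3 at -0.45 to -0.37 with the call lost each time (0.0582 to 0.114). In the right ventricle it gave 447 to 1095 higher (447, 529, 456 without KO_RV replicates 1, 2, 3 and 556 without WT_RV replicate 3), 315 to 718 lower (315, 375, 380 and 411), 11 to 17 lists, and Nos3 at -0.82 to -0.53. The interaction had 0 to 499 higher and 2 to 810 lower genes (499 and 810 without WT_RV replicate 3, 9 lower without WT_LV replicate 3, 1 higher without WT_LV replicates 1 and 3, 2 lower without KO_RV replicates 1 and 2, WT_LV replicate 2 and WT_RV replicate 1) and 10 to 15 lists. Between WT ventricles there were 45 to 1169 higher and 13 to 565 lower (67, 52, 279 and 21, 13, 96 without WT_LV replicates 1, 2, 3, and 45, 55, 1169 and 17, 14, 565 without WT_RV replicates 1, 2, 3) and 7 to 12 lists. Between KO ventricles there were 47 to 59 higher and 49 to 80 lower (80 without KO_LV replicate 1) and 14 to 18 lists. The overlap of genotype calls between ventricles, higher in KO, was 404 to 979 (404, 456, 431 without KO_RV replicates 1, 2, 3, and 447 without WT_RV replicate 3), and the overlap of genotype calls between ventricles, lower in KO, was 223 to 426 (230 and 223 without KO_RV replicates 1 and 2). Signal over background was not given per probe set, so how dimness limits single genes was not analysed here.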

Other observations

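Chosen after the results had been seen were the tests with the poly-A control term or within the low-control arrays, the set of genes called in several fits, the tests on other probe sets and around Nos3, and those on neighbouring genes, whereas the comparisons, the list tests and the splits of the arrays were planned.

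Energy and proliferation genes moved both ways in KO left ventricles. Hexokinase Hk2 rose by 1.35 and the glucose transporter Slc2a1 by 0.97, while the muscle enolase Eno3 fell by 0.69, so that 7 of 21 glycolysis genes rose and 4 fell (12 adjusted over the list alone). The glycolytic regulator Pfkfb3, of the hypoxia list, rose by 0.72, and with the poly-A control term Pfkfb3 (0.83) and Eno3 (-0.67) remained called and Hk2 (0.82) and Slc2a1 (0.68) did not. In the right ventricle Hk2 (0.76) and Slc2a1 (0.80) rose and Eno3 (-0.43) fell. Of 34 cell cycle genes 10 rose and 3 fell in the left ventricle (18 over the list alone), among them Ccnd2 (0.83) and the replication licensing genes Mcm2 (0.46) and Mcm3 (0.53), none called with the term. Of 26 antioxidant genes 5 rose and 8 fell (14 over the list alone), with Cybb, the phagocyte oxidase subunit, at 1.61 (1.29 with the term, called), Cat at 0.59, and Gsta4 (-0.65), Gpx4 (-0.55) and Prdx3 (-0.45) lower. In NO and cGMP signalling 3 of 24 rose, Prkg1 (0.66), Ddah1 (0.60) and Nostrin (0.57). In that list 4 fell, Nos3, Nos2 (-0.47), Gch1 (-0.59), which makes the cofactor of nitric oxide synthases, and Ddah2 (-0.35), with 8 over the list alone. Beside the list counts here and below, 30.9% of all genes were called in the left and 8.19% in the right ventricle. In the right ventricle Nostrin rose (0.56) and Cav1, a partner of nitric oxide synthase, fell (-0.52) with Nos3, and Nostrin and Cav1 remained called within the low-control arrays (0.66 and -0.57). The p53 target Ccng1 rose in both ventricles (0.61 and 0.69), in an apoptosis list with 7 of 23 higher and 2 lower in the left and 2 higher in the right ventricle, and that list was called higher within the low-control arrays in the right ventricle (median 0.07), where over all arrays it had adjusted p = 0.487 with an estimated correlation.

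In hypoxia response 6 of 21 rose and 2 fell in the left ventricle, and in retinoic acid signalling 2 of 17 rose and 2 fell, with Aldh1a1 at -1.33. For retinoic acid the median was 0.03 in the left ventricle, and the mean (-0.08) and camera's direction were below 0. Of 15 epicardial genes 3 rose, with Krt19 at 1.04, and 1, Tcf21, fell in the left ventricle, and Krt19 (1.24) rose and Tcf21 (-1.09) fell in the right. That list was called with the control term (medians 0.09 without and 0.73 with it) and within the low-control arrays in the right ventricle (0.16 and 0.35), whereas over all arrays without the term it had adjusted p = 0.947 in the left and 0.724 in the right ventricle with an estimated correlation. Erythroid genes, 2 of 16 higher with the embryonic globin Hba-x at 0.79 and 2 lower with Alas2 at -1.06 in the left ventricle, were called lower with the term (medians -0.32 and -0.39), and over all arrays without it had adjusted p = 0.576 with an estimated correlation. Among 8 strain-variable genes Trim12a rose and Wdfy1 (-2.32), Ifi202b (-1.67) and Alad (-1.39) fell in the left ventricle, and all 4 did the same in the right. Of 18 neighbours of Nos3 3 rose and 3 fell in the left ventricle, and 1 rose and 3 fell in the right, with Prkag2 at 0.67 and 0.82. Of 28 conduction genes 9 rose and 2 fell in the left and 0 were called in the right ventricle by limma, with 0 over the list alone. Of 14 neural crest genes 1 rose and 1 fell in the left and 1 fell in the right ventricle, and of 8 skeletal muscle genes 2 fell in the left. No Y-linked gene (3 measured) or X inactivation gene (2 measured) was called by limma in either ventricle, though 2 of 2 passed over the X inactivation list alone in the left, and Xist averaged 10.75 in KO and 12.05 in WT left ventricles (exact permutation p = 0.2).

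A set of 163 genes, 106 higher and 57 lower in KO, was called in the left ventricle with and without the control term and in the right ventricle within the low-control arrays. The last pair of fits share WT_RV replicates 1 and 2, which alone gave r = 0.363 between them in simulated data with no effect, so they are not independent and the size of the set has no chance value here. It held, at right ventricle differences, Nxpe4 (2.81), Il15, a cytokine (2.13), H2-Ab1 (1.85), Tagln (2.22), Eno2 (-2.14) and Capn3, a muscle protease (-1.98), of which Il15, Eno2 and Capn3 were named after their values were seen.

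Genotype differences of 1 or more in the right ventricle were shown in part by other probe sets: over 35 such genes with another bright probe set, that probe set showed a median share of 0.448 of the difference, and 40% showed under 0.25 of it, against 0.666 and 26.4% over 129 genes for the genotype difference in the left ventricle and 0.773 and 0% over 7 genes between KO ventricles. Sequence differences between strains under a probe set may account for some of them, which the share leaves open. Around Nos3 8.29% of 181 genes were called, against 8.19% of the others (one-sided Fisher's exact p = 0.521). This cannot decide whether a chromosome segment was carried along with the Nos3 allele. The groups are of different strains, so genes away from Nos3 may differ as much as those of a segment, and neither a short nor a long one is excluded. Strain background other than the targeted gene cannot be told apart from the allele, since the labels give 1 strain per genotype.

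Large genotype differences in the right ventricle lay next to each other more often than random placement gives. Among 155 such genes 6 neighbouring pairs had both members called at 1 or more, against a mean of 1.30 in 10000 shuffles (permutation p = 0.0023), which argues against random placement. The pairs were Hsd17b7 with 3110045C21Rik, Nipal4 with Cyfip2, Zfp429 with Zfp874a, Hapln1 with Vcan, Gatm with Spata5l1, and Inpp4b with Il15, the last with opposite signs (-1.46 and 2.13). Probe sequence shared between neighbours stays open: 5 pairs (83.3%) were left without those whose symbols share their first 3 letters, but symbols do not show shared sequence. Between KO ventricles, which are of 1 strain, 42 genes differed by 1 or more and held 1 neighbouring pair, so a pair can arise without a strain difference. No shuffles were run for that comparison. Linked regulatory differences between the strains may be a source, which was not tested, and the most genes with large right ventricle genotype differences in a window of 50 was 5, within the up to 6 of 1000 shuffles.

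With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. In the left ventricle the real split gave 5617 genes and the highest other 2, with as many in 1 split, and 18 lists against 20, with as many in 2 splits. In the right ventricle it gave 1490 genes against 0 (limma, 1 split) and 13 lists against 15 (3 splits). Between WT ventricles it gave 179 genes against 0 (limma, 1 split) and 9 lists against 16 (3 splits), and between KO ventricles 208 against 0 (limma, 1 split) and 18 lists against 10 (1 split).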
